A study of Homo sapiens with 4 samples.

How the data were processed

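RNA-seq libraries were made from total RNA of HCT116 cells, a human colon cancer cell line, with poly(A) selection and an Illumina TruSeq kit, per the labels' protocols. Of 4 samples, 2 were untreated (Control) and 2 were treated with H2O2, as their titles state. Nothing in the labels says whether the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which can be technical.

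The submitters' processing notes name CASAVA 1.8, FastQC, Trim Galore, STAR, HTSeq and DESeq, and the genome build hg19, without roles or settings. The annotation release, strand setting and dispersion settings are not given in the sources used here. The deposited file is 1 table of 16376 genes with no columns per sample. Its mean columns hold a signal, the authors' means of counts divided by size factors, per the file headers, over all libraries and over each group. Its fold column is a ratio of the 2 group means, and its log2 column is the log2 of that ratio, as deposited by the authors. Its p-value columns hold the authors' DESeq test of each gene and its Benjamini-Hochberg adjustment, per the file headers. Recomputing the overall mean, ratio and adjustment from the deposited columns gave the deposited values to within 1e-09. The header calls the groups A and B. A was taken as Control and B as H2O2 from the order of the groups in the table's name and the authors' tool's habit of dividing the later group by the earlier, so every direction rests on that order. The lowest mean over both groups was 5.46, so genes of lower mean are not analysed here.

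Each group mean is a sum of 2 whole counts, each divided by its library's size factor and by 2. The 2 steps were found from the low values and refined by least squares, and each mean was solved for a pair of whole counts within a tolerance of 1e-09. All 16376 genes had exactly 1 solution in each group, with residuals of at most 4.55e-11. Size factors computed from the recovered counts as medians of ratios equalled the recovered steps to 1.33e-15 or better. In simulated tables of 16376 genes the counts came out exactly for 100% of genes. The table does not tie a recovered library to a replicate number. Total counts over listed genes were 7309731 and 6892854 for Control and 7365032 and 6858809 for H2O2, with 2.11% to 2.30% of reads in the 10 highest genes. No pair of libraries agreed within sampling noise, and none was treated as a duplicate.

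The main result is the authors' test at an adjusted p under 0.05, the choice written for a table of group means. As an added alternative, chosen after the values were seen, limma 3.58.1 in R 4.3.3 was run with a mean-variance trend on log2(normalized count + 1) of the recovered libraries. Adjusted p-values outside the authors' table are limma's with Benjamini-Hochberg adjustment, and its fold changes are on the log2(value + 1) scale, which understates low genes. In a simulation of H2O2 against Control on 16376 genes, 200 of them changed, limma found 62% of genes changed 1.5-fold, 96% of those changed 2-fold, 100% at 3-fold and 98% at 4-fold, with 9 false calls among 187. With no gene changed it made 0 calls. The simulated genes varied independently, with the same dispersion in both groups and no length trend. These rates may therefore not hold for the recovered libraries.

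The 28 gene lists, the markers of 4 other cell types, the main test, the alternatives other than those called added, and the rule for named genes were fixed before the data were examined. List members with a mean normalized count of at least 10 count as measured. For each list the members past the threshold were counted over all genes and adjusted over the list alone. The median log2 fold change was placed among those of 10000 random lists of the same size, drawn from the 200 genes nearest in mean expression to each member, as a description of these libraries. camera, with a preset correlation of 0.01 and with an estimated one, and fry were added on the recovered libraries, with 2 residual degrees of freedom. Named genes are the 15 largest rises and 15 largest falls among genes past the threshold with a mean of at least 50 and groups that do not overlap. They also include the 5 members of each list with the smallest adjusted p, all members of the peroxide removal and NRF2 lists with a mean of at least 50, and the control genes ACTB, GAPDH, NFE2L2, KEAP1 and MYC. Some genes that the rule names are not reported here. The cell type markers are named from their fixed lists, and other genes outside this rule were chosen after their values were seen.

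Exonic lengths, gene classes and overlaps came from GENCODE release 29, matched by symbol or synonym for 85.0% of listed genes, 82.2% of higher and 88.5% of lower calls. That release is on another build than the table, so no coordinates are given. Sequence shared with other genes was measured as the percent of 75-base words of a gene's longest transcript found in other genes' transcripts on either strand. The length correction removed from each library a smooth trend (lowess, span 0.3) of its deviation from the gene's mean on exonic length.

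Alternatives were other thresholds and filters, centring, equal totals, a pseudocount of 0.5 or 5, voom weights, each library left out in turn (limma), the length correction, and for lists other minimum means, unmatched random lists and the list without its most changed member. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.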

Results

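Gene expression was measured by RNA-seq in HCT116, a human colon cancer cell line, with and without exposure to hydrogen peroxide (H2O2), an oxidant that crosses cell membranes. The labels name 2 Control samples and 2 H2O2 samples and give neither a dose nor an exposure time. The deposited values are group means of normalized counts for 16376 genes, together with the authors' test of each gene. Whole read counts of the 4 libraries behind these means were recovered by solving each mean for a pair of whole counts. The control libraries held 7309731 and 6892854 reads over the listed genes and the H2O2 libraries 7365032 and 6858809 reads, called the deeper and the shallower library of each group below because the table carries no replicate numbers. The table calls its groups A and B, and A was taken as Control from the order of the groups in its name, so all directions rest on that order. The question put to the data was which genes differ between H2O2-treated and untreated cells.

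With H2O2, 22 of 29 immediate early and AP-1 genes, 11 of 19 heat shock genes and 8 of 30 p53 target genes were higher in the authors' deposited table, and none of these lists held a gene called lower. Of 13 mitochondrially encoded mRNAs, 8 were lower in the authors' deposited table, of which limma called 6. FOSB rose 16.7-fold, EGR2 7.57-fold, FOS 5.07-fold and JUN 5.04-fold in the authors' deposited table. MT-CO1, the mitochondrially encoded subunit 1 of cytochrome c oxidase, fell to 0.166 of its control mean in the authors' deposited table. Of 20 genes that remove peroxide and superoxide, none passed the threshold of the authors' test or of limma with all 4 libraries. At an unadjusted p under 0.05 the authors' test gave 3 and limma 3. Their median log2 fold change was 0.18 in the authors' deposited table, 0.32 without the shallower control and 0.056 without the deeper.

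At an adjusted p under 0.05, 1178 genes (7.19% of those listed) differed in the authors' deposited table, 422 higher and 756 lower with H2O2. Changes of at least 2-fold were found for 235 of the higher and 126 of the lower genes in the authors' deposited table. limma on the recovered libraries called 671 genes, 249 higher and 422 lower, and all 671 were among the authors' calls in the same direction. Each library was then left out in turn, which leaves a group with a lone library. Without a control, the spread came from the H2O2 libraries alone, which differed less from each other than the controls did. Counts and p-values of those fits, here and below, thus leave out the spread between the controls. Without the deeper control library limma called 1396 genes, without the shallower control 3641, without the deeper H2O2 library 284 and without the shallower 512. Of the 671 genes, 182 were called in all 4 of these fits.

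**Figure D1:**
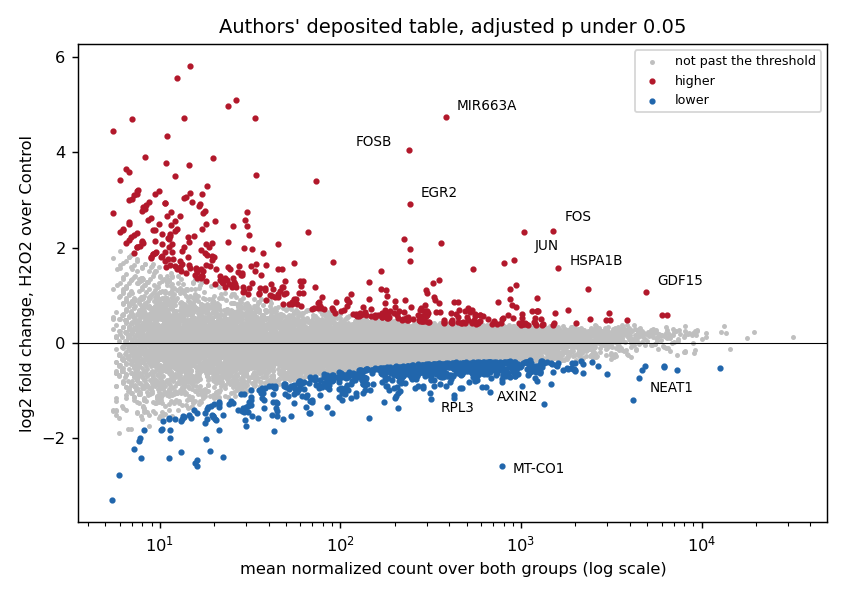
Log2 fold change (H2O2 over Control) of each gene with a nonzero control mean against its mean normalized count over both groups (log axis), from the authors' deposited table, with genes past an adjusted p of 0.05 in red (higher) and blue (lower). MIR663A, FOSB and EGR2 lie highest among the labelled genes, and MT-CO1 lies lowest of the labelled genes at -2.59.

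The immediate early and AP-1 genes, which encode transcription factors and phosphatases induced rapidly by many stimuli, were mostly higher. Of 29 measured members, 22 were higher, none lower and 7 not past the threshold in the authors' deposited table, and 25 were higher when adjusted over the list alone. Their median log2 fold change of 0.82 in the authors' deposited table lay above those of all 10000 random lists matched on expression. FOSB went from 27 and 28 control reads to 426 and 479 reads with H2O2 (limma, adjusted p = 6.44e-09). EGR2 rose by 2.91 ± 0.16 on the log2 scale (SE, 2 libraries per group, limma, adjusted p = 9.67e-08), FOS by 2.35 ± 0.16 (8.79e-07) and JUN by 2.33 ± 0.16 (6.80e-07). DUSP2 and DUSP1, which encode phosphatases of MAP kinases, had log2 fold changes of 2.09 and 1.97 in the authors' deposited table. ATF3 and the nuclear receptor gene NR4A1 had log2 fold changes of 1.74 and 1.68 in the authors' deposited table. The list's median was already 0.38 higher on the log2 scale in the shallower than in the deeper control library. limma called 19 of the 29, and 15 of them passed in all 4 fits with a library left out.

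Of 19 measured heat shock protein and co-chaperone genes, 11 were higher, none lower and 8 not past the threshold in the authors' deposited table. Adjusted over the list alone, 15 were higher. The median log2 fold change was 0.49 in the authors' deposited table, above all matched random lists, and the list's median was 0.26 higher in the shallower than in the deeper control library. DNAJB1, a cofactor of HSP70, rose by 0.94 ± 0.14 and HSPH1 by 0.92 ± 0.11 on the log2 scale (limma, adjusted p = 0.00161 and 3.42e-04). BAG3, a co-chaperone, rose by 0.69 ± 0.13 on the log2 scale (limma, adjusted p = 0.00883) and did not pass without the shallower H2O2 library (0.0664). Of the 10 members that limma called, 4 passed in all 4 fits with a library left out. HSPA1B rose 2.97-fold in the authors' deposited table, an uncertain value because 73.2% of its 75-base words also occur in transcripts of other genes.

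**Figure D2:**
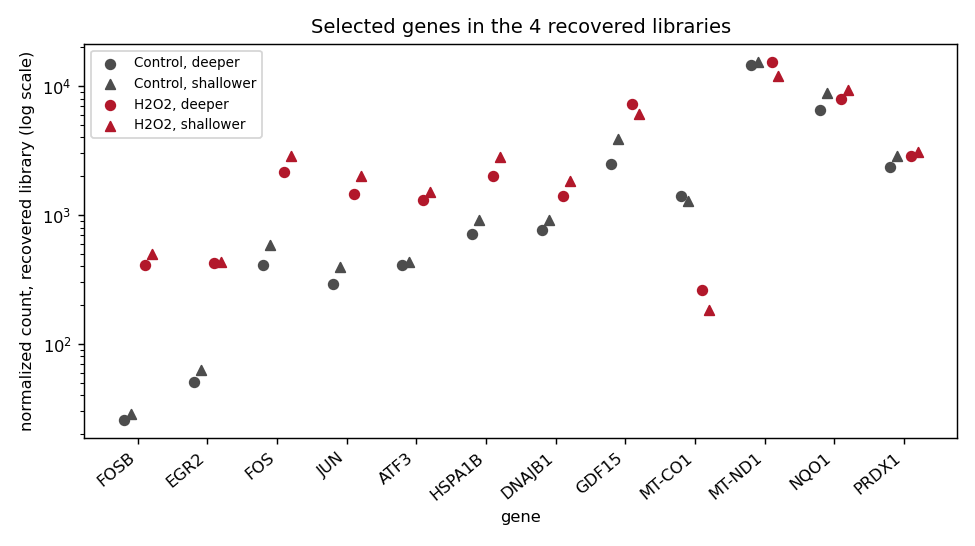
Normalized counts of 12 genes (log axis) in the 4 libraries recovered from the group means, with controls in grey and H2O2 in red, circles for the deeper and triangles for the shallower library of a group. The H2O2 libraries lie above both controls for FOSB, EGR2, FOS, JUN, ATF3, HSPA1B, DNAJB1 and GDF15 and below them for MT-CO1, while for MT-ND1 and NQO1 the groups overlap.

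Among p53 target genes, 8 of 30 measured members were higher, none lower and 22 not past the threshold in the authors' deposited table, and 9 were higher when adjusted over the list alone. The list's median of 0.072 in the authors' deposited table stood at percentile 82.7 of matched random lists. It was 0.14 (percentile 99.3) without the deeper H2O2 library and 0.033 (percentile 62.4) without the shallower. Between the controls the list's median was 0.11 higher in the shallower than in the deeper library. limma called 7 members, and 3 passed in all 4 fits with a library left out. GDF15, a secreted stress cytokine, rose by 1.09 ± 0.17 on the log2 scale (limma, adjusted p = 0.00221). PMAIP1 and BBC3, which encode the BH3-only proteins NOXA and PUMA, had log2 fold changes of 0.86 and 0.61 in the authors' deposited table, and the growth arrest gene GADD45A had one of 0.75. BBC3 did not pass in limma without the deeper H2O2 library (adjusted p = 0.211). PMAIP1 and BBC3 were also the 2 risen genes among 14 measured BCL2 family members, of which 12 did not pass, and both were past the threshold adjusted over the list alone (median 0.15, percentile 98.6, and 95.7 without the shallower control). Their median was 0.24 without the deeper H2O2 library.

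Among the ATF4 and amino acid stress genes, DDIT3 (CHOP, an uncertain value with 24.8% of its words shared with other genes) and PPP1R15A (GADD34) rose 2.31-fold and 2.18-fold in the authors' deposited table, and the glutathione-degrading enzyme gene CHAC1 fell to 0.648 of its control mean. CHAC1 did not pass in limma without the deeper or the shallower H2O2 library (adjusted p = 0.0545 and 0.291). The other 17 of 20 did not pass, and adjusted over the list alone 2 were higher and 2 lower (median 0.15, percentile 98.5, and 91.2 without the shallower control, 95.3 without the deeper H2O2 library or 59.2, with a median of 0.053, after the length correction). camera did not call the list after that correction (adjusted p = 0.128). Of 20 genes of the endoplasmic reticulum unfolded protein response, MANF and DNAJB9 were the 2 past the threshold, both higher, in the authors' deposited table, and 4 were higher adjusted over the list alone (median 0.18, percentile 99.2, and 96.6 with a median of 0.12 without the deeper control, or 92.0 after the length correction). With all 4 libraries neither MANF nor DNAJB9 passed in limma (adjusted p = 0.0635 and 0.0883). The median of the unfolded protein response list was 0.24 without the shallower control. Of 16 NF-kB and inflammatory genes, NFKBIA rose 1.88-fold and IL8 2.27-fold in the authors' deposited table, 14 did not pass, and 3 were higher adjusted over the list alone (median 0.16, percentile 98.9). The list's median was 0.14 higher in the shallower than in the deeper control library. It stood at 0.024 without the deeper control (percentile 66.2) and at 0.043 without the shallower H2O2 library (percentile 71.9), and IL8 did not pass in limma without the latter (adjusted p = 0.165).

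**Figure D3:**
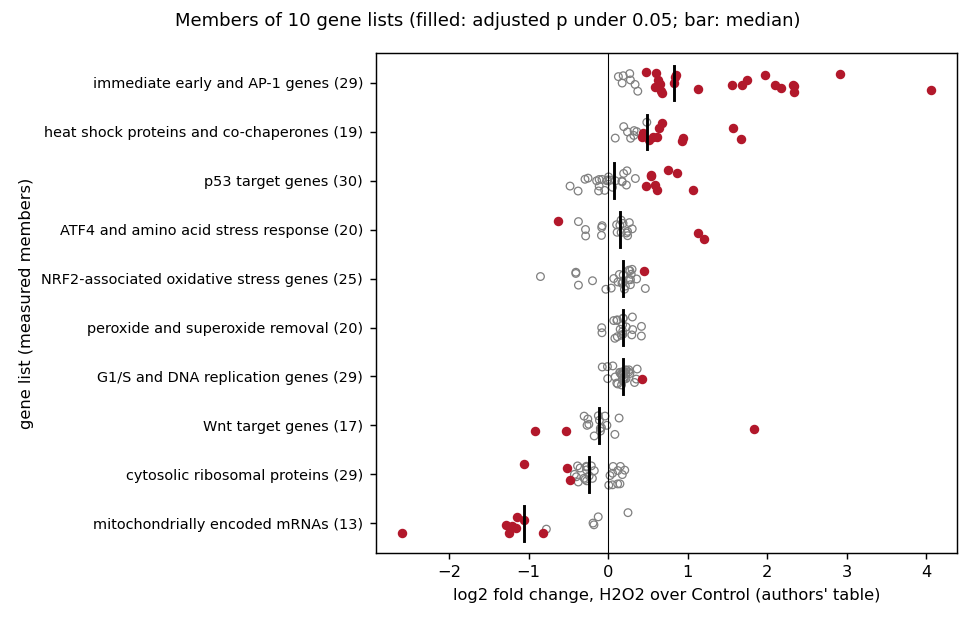
Log2 fold changes (H2O2 over Control, authors' deposited table) of the measured members of 10 gene lists, with the number of members in brackets, filled points for members past an adjusted p of 0.05 and a bar at each list's median. The immediate early median lies at 0.82, the heat shock median at 0.49 and the mitochondrial median at -1.05.

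None of 20 measured peroxide and superoxide removal genes passed in the authors' deposited table, over all genes or adjusted over the list alone. Peroxiredoxin PRDX1 (26.5% of words shared with other genes) stood at a log2 fold change of 0.19, catalase (CAT) at 0.084 and superoxide dismutase SOD1 at 0.31 in the authors' deposited table. HMOX1, which encodes heme oxygenase 1, was the 1 higher gene among 25 NRF2-associated genes, 24 did not pass, and none passed adjusted over the list alone in the authors' deposited table. It rose 1.37-fold there (adjusted p = 0.0470) and did not pass in limma (adjusted p = 0.0892). Without the shallower control library the median log2 fold changes of the peroxide and NRF2 lists were 0.32 and 0.34, and without the deeper control 0.056 and -0.010. Without the deeper H2O2 library they were 0.13 and 0.25, and without the shallower 0.15 and 0.065. NQO1, GCLM and TXNRD1 had log2 fold changes of 0.17, 0.28 and -0.030 in the authors' deposited table. The medians of the peroxide and NRF2 lists were 0.27 and 0.20 higher in the shallower than in the deeper control library. These medians, 0.18 and 0.19 with H2O2 over Control, lay at percentiles 99.7 and 99.9 of matched random lists, and at 76.0 and 25.3 without the deeper control library. Without the shallower H2O2 library the NRF2 list stood at 68.4, and without the deeper one the peroxide list at 96.8. Without the shallower control both lay above 99.9, and after the length correction they stood at 70.8 and 87.6. NFE2L2, which encodes NRF2, and its repressor KEAP1 did not pass, at log2 fold changes of 0.17 and 0.28 in the authors' deposited table.

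Mitochondrially encoded mRNAs fell in 8 of 13 cases, none rose and 5 did not pass in the authors' deposited table, and 9 were lower adjusted over the list alone. limma called 6 of the 13, and 5 passed in all 4 fits with a library left out. Their median log2 fold change of -1.05 in the authors' deposited table lay below those of all matched random lists. MT-CO1 went from 1457 and 1247 control reads to 272 and 175 reads with H2O2, and fell by 2.61 ± 0.15 on the log2 scale (limma, adjusted p = 1.12e-07). MT-ND5 and MT-ND4, subunits of complex I, had log2 fold changes of -1.21 and -1.15 in the authors' deposited table. MT-ND6 had one of -1.28 in the authors' deposited table, an uncertain value because it is encoded on the opposite strand to the other mRNAs and the strand setting of the counting is not stated. MT-CO1 is uncertain too, because 36.6% of its 75-base words occur in nuclear transcripts. None of 26 nuclear-encoded respiratory chain genes passed in the authors' deposited table or adjusted over the list alone, with 2 at an unadjusted p under 0.05 there and 4 in limma, which called none with all 4 libraries and 13 higher without the shallower control. Their median of 0.17 stood at percentile 99.8, at 97.2 without the deeper control library and at 85.4 after a correction for transcript length.

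Of 29 cytosolic ribosomal protein genes, 3 fell, none rose and 26 did not pass in the authors' deposited table. Adjusted over the list alone 5 were lower, and the list's median was -0.24 (percentile 0). Medians were smaller for all genes of mean at least 50 with the symbol stem RPL (-0.086, 46 genes) or RPS (-0.12, 39 genes). Of these 4 (8.70%) and 2 (5.13%) were lower, against 5.43% of all genes of such a mean. Such stems were read from the symbol alone and can hold genes that do not encode ribosomal proteins. RPL3 fell by 1.06 ± 0.13 on the log2 scale (limma, adjusted p = 2.94e-04), and limma called 2 members in all. RPL37 had a log2 fold change of -0.48 in the authors' deposited table. RPL3 is uncertain, as 19.1% of its words also occur in other genes' transcripts, against 0.0525% for RPL37. RPL37 did not pass in limma without the deeper or the shallower H2O2 library (adjusted p = 0.192 and 0.287).

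Among 17 Wnt target genes AXIN2 and RNF43, feedback inhibitors of the pathway, fell to 0.529 and 0.690 of their control means in the authors' deposited table. Both values are uncertain, as 29.7% of the 75-base words of AXIN2 and 76.2% of those of RNF43 also occur in transcripts of other genes. The stem cell marker LGR5 rose from 7 and 10 to 40 and 21 reads, 14 did not pass, and the counts were the same, 1 higher and 2 lower, adjusted over the list alone (median -0.11, percentile 2.88, and 8.11 with a median of -0.059 without the deeper control). In limma RNF43 did not pass without the deeper or the shallower H2O2 library (adjusted p = 0.192 and 0.156), nor did LGR5 without the deeper (0.307). Of 11 long noncoding RNAs, NEAT1, MALAT1 and SNHG12 were the 3 that fell, both over all genes and adjusted over the list alone, with 8 not past the threshold in the authors' deposited table (median -0.078, percentile 10.1, and 61.8 with a median of 0.073 without the shallower H2O2 library). NEAT1 fell to 0.601 of its control mean in the authors' deposited table, in counts per gene from poly(A)-selected RNA that do not separate isoforms. In limma it did not pass without the deeper H2O2 library (adjusted p = 0.0922), nor did MALAT1 (0.112) or SNHG12 (0.499), and the last 2 also did not without the shallower (0.446 and 0.178).

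The cell cycle lists held few calls. PCNA rose 1.34-fold in the authors' deposited table as the 1 gene past the threshold among 29 G1/S and DNA replication genes, also adjusted over the list alone, and the list's median was 0.19. PCNA did not pass in limma without the deeper or the shallower H2O2 library (adjusted p = 0.326 and 0.347). The proliferation marker MKI67 was the 1 of 29 G2/M and mitosis genes past the threshold, also adjusted over the list alone. The list's median was 0.094 (percentile 85.7), 0.17 without the deeper control (percentile 99.99) and 0.082 without the shallower (percentile 64.1). MKI67 was lower, at a log2 fold change of -0.49 in the authors' deposited table. It had 7497 and 4132 control reads against 4155 and 3954 with H2O2, and limma did not call it (adjusted p = 0.178). Without the deeper control limma called 7 G2/M genes higher and none lower, and without the shallower 4 higher and 6 lower. Only 9 of 23 fixed histone genes were measured in these poly(A)-selected libraries, which miss transcripts without a poly(A) tail. The list therefore does not measure histone genes as a whole. Of the 9 histone genes H2AFJ alone passed, 1.59-fold higher in the authors' deposited table, also adjusted over the list alone (median 0.12, percentile 82.4). The list's median was -0.091 without the deeper control (percentile 23.8) and 0.38 without the shallower (percentile 99.0). H2AFJ did not pass in limma without the deeper or the shallower H2O2 library (adjusted p = 0.209 and 0.0513). RAD51C was the 1 higher gene among 24 of double-strand break repair in the authors' deposited table, and none passed adjusted over the list alone (median -0.047, percentile 19.1), nor did RAD51C in limma (adjusted p = 0.0549). None of 21 base excision repair genes passed either way in the authors' deposited table, nor in limma, with 4 at an unadjusted p under 0.05 in each (median 0.088, percentile 93.0). Without the shallower control limma called 5 of them higher and 1 lower, and without the deeper control, where the list stood at percentile 48.7, 2 higher and 1 lower. The double-strand break list stood at percentile 96.3 without the deeper control and at 1.07 without the shallower, where limma called 6 of its members lower and 1 higher. Among 26 enzymes of DNA and histone methylation and acetylation, TET3 was lower in the authors' deposited table, 7 were lower adjusted over the list alone, and the median was -0.14 (percentile 0.990). The list's median differed by -0.14 between the shallower and the deeper control library too, and without the deeper control it was -0.068 with H2O2 (percentile 8.51). limma did not call TET3 (adjusted p = 0.193).

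Of 12 mesenchymal transition genes, 2 were higher in the authors' deposited table, among them the transcription factor gene SNAI1, which rose 2.87-fold there. The other 10 did not pass, and 3 were higher adjusted over the list alone (median 0.15, percentile 96.8, and 77.2 with a median of 0.060 without the deeper control). Of 15 epithelial identity genes, ELF3 rose 1.61-fold and the tight junction gene CLDN4 1.39-fold in the authors' deposited table, 13 did not pass, and the same number of 2 were higher adjusted over the list alone (median 0.14, percentile 95.3, and 50.9 with a median of 0.047 without the shallower control). The zinc exporter gene SLC30A1 rose 1.55-fold in the authors' deposited table as the 1 call among 5 metallothionein and zinc genes, with 2 higher adjusted over the list alone (median 0.35, percentile 99.7). Without the deeper control that median was 0.20 and its percentile fell outside the upper 2.5 points. In limma SLC30A1 and CLDN4 did not pass without the shallower H2O2 library (adjusted p = 0.263 and 0.196), nor CLDN4 and ELF3 without the deeper (0.409 and 0.0775). ANKRD37 was the 1 higher gene of 25 hypoxia and glycolysis genes (median 0.15, percentile 96.3) and IDI1 that of 21 cholesterol synthesis genes (median -0.019, percentile 28.7) in the authors' deposited table, each also adjusted over the list alone. ANKRD37 is uncertain, with 61.1% of its words shared with another gene's transcripts. limma called neither ANKRD37 nor IDI1 (adjusted p = 0.147 and 0.0601). The hypoxia list's median was 0.47 higher in the shallower than in the deeper control library. Without the deeper control it was -0.043 (percentile 4.92) and limma called 3 members lower, and without the shallower it was 0.43, above all matched random lists, and limma called 18 higher. The cholesterol list stood at percentile 86.4 without the deeper control and 96.3 without the deeper H2O2 library. The cholesterol list had a mean of 0.028 and the iron list one of 0.0032, opposite in sign to their medians, and camera gave both the direction up. No gene passed in the authors' deposited table among 16 interferon-stimulated, 20 autophagy and lysosome and 11 iron handling genes, nor adjusted over each list alone. Their medians were 0.020 (percentile 60), 0.11 (percentile 91.8) and -0.042 (percentile 23.7). The autophagy list stood at percentile 99.15 after the length correction and at 72.2 without the deeper control. Without that control the iron list stood at 67.8, with a median of 0.047. limma called no gene of these lists either. At an unadjusted p under 0.05 the authors' test gave 1, 2 and 0 of them and limma 2, 2 and 0. Without the shallower control limma called 2 interferon-stimulated and 5 autophagy genes higher and 1 iron handling gene lower. The control genes ACTB, GAPDH and MYC did not pass, at log2 fold changes of 0.34, 0.13 and -0.26 in the authors' deposited table.

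Outside the lists, MIR663A rose most among the genes named by size, from 30 and 26 control reads to 806 and 675 reads with H2O2, 26.7-fold in the authors' deposited table. Its reads map to the annotated locus of a microRNA hairpin inside a longer host RNA, MIR663AHG, and the 2 cannot be told apart. BZRAP1 rose 10.5-fold in the authors' deposited table, with 18 and 8 control reads against 182 and 88, and has an exon that overlaps an antisense gene. RHBDL1, GNRH1 and the chaperone gene FKBP11 fell to 0.333, 0.360 and 0.388 of their control means in the authors' deposited table. FKBP11 and CCDC65, which also fell (log2 fold change -1.47 in the authors' deposited table), overlap each other on opposite strands. Exons of 7 of the 13 annotated genes among the 15 largest falls overlap another gene, as do those of 5 of 13 among the 15 largest rises. DNAJB1, DNAJB9, DDIT3, NR4A1, BBC3, ELF3, LGR5, IDI1, RNF43, ANKRD37, MALAT1, SNHG12, PRDX1, NQO1, NFE2L2 and GAPDH also overlap a gene on the opposite strand, and their values are uncertain as the strand setting of the counting is not stated. AXIN2, RPL3, NEAT1, HSPA1B and MT-ND4 overlap a gene on their own strand, which no strand setting separates. So do DDIT3, BBC3, ELF3, RNF43, MALAT1, SNHG12, NFE2L2 and FKBP11, beside their overlap on the opposite strand.

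Markers of other cell types were few. Of 3 measured fibroblast markers, COL1A1 was lower, at 0.734 of its control mean in the authors' deposited table, also adjusted over the list alone, and COL3A1 and PDGFRB did not pass. Of 4 listed leukocyte markers, CD79A and CD14 were higher in the authors' deposited table. CD79A had 0 and 2 control reads against 23 and 19, and CD14 had 5 and 3 against 19 and 10 and did not pass in limma (adjusted p = 0.0794). CD68 and CD74 did not pass, nor did the endothelial marker KDR or the erythroid marker HBA1.

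The control libraries differed more from each other than the H2O2 libraries did. The chi-square per gene, which is 1 for sampling noise alone, was 7.15 between the controls and 2.38 between the H2O2 libraries, against 12.9 and 11.7 for the deeper control and 6.73 and 5.99 for the shallower control with the H2O2 libraries. Longer transcripts were lower with H2O2, with a Spearman rho across 11298 genes of -0.45 between exonic length and the log2 fold change of the authors' deposited table. Against the deeper control alone rho was -0.53 and against the shallower alone -0.22. The ratio of the shallower to the deeper control library had a like trend (rho -0.45), and the ratio of the H2O2 libraries had one of 0.13. Genes are not independent replicates in such a correlation. Among the 2259 genes with the longest transcripts 301 were lower and 8 higher in the authors' deposited table, and among the 2260 with the shortest 48 were lower and 101 higher.

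**Figure D4:**
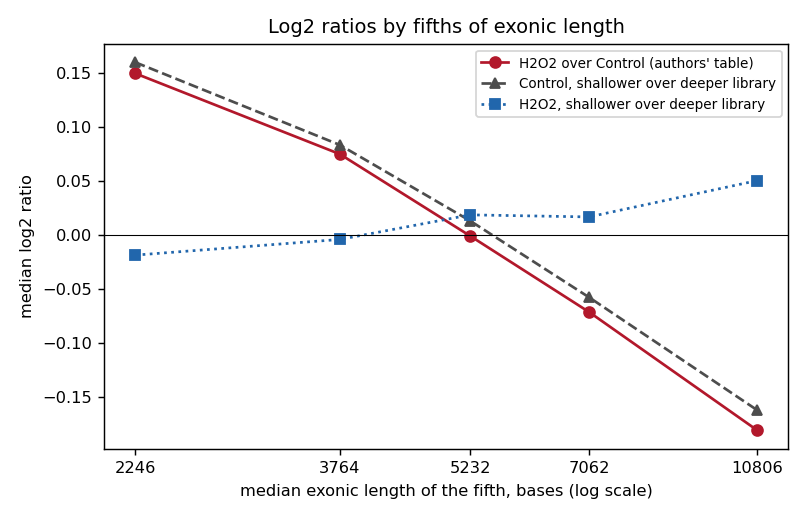
Median log2 ratio in 5 groups of genes by exonic length (median length of each group in bases, log axis) for H2O2 over Control from the authors' deposited table (red), the shallower over the deeper control library (grey) and the shallower over the deeper H2O2 library (blue). The red medians go from 0.15 to -0.18 and the grey ones from 0.16 to -0.16.

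On the recovered libraries, camera with a preset correlation of 0.01 called 19 of the 28 lists at an adjusted p under 0.05, with the immediate early list first (adjusted p = 2.60e-36), and 11 after the length correction. With an estimated correlation camera called none, the smallest adjusted p being 0.449, shared by most lists, the immediate early list among them, and 2 lists had an unadjusted p under 0.05. fry called 1 list, G1/S and DNA replication (adjusted p = 0.0336), and gave 7 an unadjusted p under 0.05. By percentile among matched random lists, 14 of the 28 lists lay within 2.5 points of either end, and 7 of those 14 also did without the deeper control library, as did 7 after the length correction. The immediate early, heat shock, G1/S, ribosomal protein and mitochondrial lists were the 5 that did so in all 7 settings, the calculation given above included.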

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

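All limma fits, the leave-one-out values, the length correction and the set tests were chosen after the data were seen, and the other alternatives were planned. Of 1178 genes changed by H2O2 in the authors' deposited table (422 higher, 756 lower), an adjusted p under 0.01 left 642 (242 higher, 400 lower), a 2-fold minimum 361 (235 and 126), and a 2-fold minimum on means + 1 left 356 (232 and 124). With a mean of at least 50 there were 219 higher genes, and limma on the recovered libraries called 671 (249 higher, 422 lower). Stricter thresholds lower these counts by construction, and for limma the cause was not tested. Centring and equal group totals shift all genes alike by almost nothing here, and means + 1 cannot turn a sign, so these say nothing of how stable the directions are. With a library left out limma called 284 to 3641 genes (104 to 1741 higher, 180 to 1900 lower), and the lone library of a group was then assumed to vary like the others. Its count stayed within 1.5 times of 671 under voom, other pseudocounts and equal totals. With a mean of at least 10 it was 655, 634 of them among the 671, and with a mean of at least 50 it was 460, 122 higher against 249. No paired analysis was possible because the recovered libraries carry no replicate numbers. Count tests that need raw counts per sample were not run.

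With a library left out, the medians of the immediate early, G2/M and autophagy lists moved by less than the spread between libraries, from 0.73 to 0.96, 0.062 to 0.17 and 0.049 to 0.14. The other lists moved by more in at least 1 of the 4 settings, and the cause was not tested. That spread was computed from the same library differences that cause these moves, so it grows where a list's libraries disagree. Comparing a move with it therefore does not tell which lists are stable. The G1/S list counted as moved at medians of 0.16 to 0.21, while G2/M did not at percentiles of 64.1 to 99.99. Without the deeper control 8 of 28 lists moved by less than that spread, without the shallower control 13, without the deeper H2O2 library 23 and without the shallower 21. The ranges were -0.010 to 0.34 for NRF2-associated genes, lowest and reversed at -0.010 without the deeper control, 0.056 to 0.32 for peroxide removal, 0.033 to 0.14 for p53 targets and 0.33 to 0.54 for heat shock. They were 0.12 to 0.24 for the unfolded protein response, 0.13 to 0.17 for ATF4, 0.16 to 0.21 for G1/S, -0.091 to 0.38 for histones and 1.40e-04 to 0.16 for base excision repair. They were -0.18 to 0.093 for double-strand break repair, 0.17 to 0.24 for BCL2 family, 0.024 to 0.28 for NF-kB, 0.0051 to 0.054 for interferon-stimulated and -0.043 to 0.43 for hypoxia genes. They were -0.036 to 0.13 for cholesterol synthesis, -1.28 to -0.61 for mitochondrial mRNAs, 0.10 to 0.24 for the nuclear respiratory chain and -0.26 to -0.15 for ribosomal proteins. They were 0.20 to 0.49 for metallothioneins, -0.15 to -0.059 for Wnt targets, -0.16 to -0.068 for methylation and acetylation enzymes and 0.047 to 0.14 for epithelial genes. They were 0.060 to 0.21 for mesenchymal genes, -0.050 to 0.047 for iron handling and -0.084 to 0.073 for long noncoding RNAs.

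With the length correction the median was 0.12 for the unfolded protein response, 0.053 for ATF4, 0.14 for G1/S, 0.036 for cholesterol synthesis, 0.089 for the respiratory chain, 0.19 for metallothioneins and 0.061 for iron handling. A mean of at least 1 gave 0.059 for interferon-stimulated genes, a mean of at least 50 gave -0.82 for mitochondrial mRNAs, and long noncoding RNAs stood at -0.024 without the member of the largest change. Of 196 named genes, 187 kept their side of the threshold in limma, and 9 called by the authors did not pass it. The 187 include genes called by neither test. Over all genes, 507 of the authors' 1178 calls did not pass in limma. Genes near the lowest listed mean of 5.46 rest on as few as 22 reads over 4 libraries.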

Other observations

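The length correction, the tests of mitochondrial RNA as a whole and of mRNAs with under 1% shared sequence, the other splits of the libraries and the tests of gene classes and symbol families were chosen after the results were seen. Of 422 genes higher with H2O2 in the authors' deposited table, 143 (33.9%) had a control mean under 10 normalized counts. S100P, a calcium-binding protein gene, went from 3 and 2 control reads to 82 and 49 reads. SNORD3D, a small nucleolar RNA, went from 5 and 6 to 68 and 58 in these poly(A)-selected libraries, which do not measure its total level. SEMA4A went from 2 and 3 reads to 47 and 27, the cytokine gene LTA from 10 and 6 to 58 and 29, and the long noncoding RNA HOTTIP from 6 and 5 to 31 and 30. These genes were chosen after their values were seen.

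Of 682 genes annotated as long noncoding RNAs, 33 (4.84%) were higher in the authors' deposited table, against 2.37% of other genes (odds ratio 2.09, Fisher's exact test, adjusted p = 0.00133 over 8 tests). In random sets matched on mean expression 28.9 were higher on average, and 2381 of 10000 sets held at least 33. The excess was thus not beyond that of such sets. They were drawn from all annotated genes of like level, long noncoding RNAs included, which can hide an excess. They were called lower less often than other genes (2.93% against 4.91%, adjusted p = 0.0334), small RNAs were called higher in 3 of 21 cases (adjusted p = 0.0334), and protein-coding genes were called higher less often than other genes (2.35% against 4.94%, adjusted p = 5.06e-04), all by Fisher's exact test and not matched on expression. The other 4 of the 8 tests did not pass. Of 130 families of genes sharing a symbol stem, none passed in 260 one-sided Fisher's exact tests, the smallest adjusted p being 0.0827 for CDKN and HSPA, each with 3 of 10 members higher.

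Longer transcripts were lower with H2O2 in the authors' deposited table (rho -0.45 across 11298 genes, and -0.53 against the deeper or -0.22 against the shallower control alone). Annotated retained introns were argued against, since among 4646 genes with no such transcript rho was still -0.43 (-0.427). The trend as the whole cause of the limma calls was argued against too, since 84.7% of those on genes with a length (483 of 570) passed after the length correction. Of these calls, 190 of 202 higher and 293 of 368 lower ones stayed, and 684 genes were called after the correction. Whether the trend caused the authors' calls that limma did not make was not tested. A yield of long transcripts that varies between libraries is a candidate explanation of the trend, as the ratio of the control libraries, which differ in no treatment, had a rho of 0.448 in size. An effect of H2O2 on long transcripts stays open beside it.

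For the 143 genes near silent in the controls, counting noise was argued against, as 35 genes called lower had an H2O2 mean under 10, a ratio of 4.09. Read-through from an upstream gene may contribute and stays open, because 71.3% of the 143 had an annotation, too few for the test. In that test 53.8% of 78 genes had an expressed gene upstream against 52.4% of 506 uncalled ones, a difference of 1.44 points (permutation p = 0.877). For upstream genes on the opposite strand the difference was 13.9 points. A response of these genes to H2O2 stays open as untested.

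Of 13 mitochondrially encoded mRNAs, 8 fell in the authors' deposited table, and a lower level of mitochondrial RNA as a whole was argued against. The 4 with the most reads, MT-ND1, MT-CYB, MT-ND3 and MT-CO3, had a median log2 fold change of -0.152 (-0.37 to 0.038 with a library left out) against -1.15 for the other 9 (-1.36 to -0.71). Of 6 mRNAs with under 1% of words shared with annotated nuclear transcripts, 3 were lower, MT-ND5, MT-ND4 and MT-ND4L. For those 3 this argued against such shared words as the cause. MT-ND4 and MT-ND4L overlap on the same strand, so they are not separate cases. This rule and that for mitochondrial RNA as a whole were written after the results were seen. Nuclear copies outside the annotated transcripts, or copies that differ in sequence, were not measured, so reads shared with them stay open as a cause. Over all 13, sharing may still contribute, since rho of shared sequence with the log2 fold change was -0.124 (bootstrap interval -0.713 to 0.493, permutation p = 0.688). The libraries hold poly(A)-selected RNA, so total levels of these mRNAs were not measured. An effect of H2O2 on single mitochondrial mRNAs stays open as a hypothesis.

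The 4 libraries allow 3 splits into 2 and 2, too few for a share under 0.05, and only 1 of the 3, the real one, gave as many genes. limma called 671 genes in the real split and 0 in each of the others, which had 113 and 179 genes at an unadjusted p under 0.05. Each other split puts 1 control and 1 H2O2 library in each group, so any difference between Control and H2O2 adds to the spread within its groups. Few calls were thus likely in advance, and these splits cannot tell whether the 671 calls arose by chance.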
